A study of Rattus norvegicus with 29 samples.

How the data were processed

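RNA was measured by poly-A enriched, stranded RNA sequencing of whole C6 to C8 dorsal root ganglia from 29 rats, 1 library per rat. Per the labels, RNA integrity numbers were above 7.6 with a mean of 8. The sample labels name a sham group where the series text names naïve rats, and the labels' word is used here. Rat numbers were unique to 1 library each, so weeks were compared between animals and no samples were paired.

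The authors list bcl2fastq 1.8.4, TopHat2, Picard and HTSeq and the genome build rn6 (Rnor_6.0), without the role of each tool. The deposited files hold read counts per RefSeq transcript after removal of duplicates, as whole numbers without normalization. Each of 29 larger files held 18092 transcripts (17501 with the prefix NM and 591 with NR) and 5 summary lines with reads outside annotated features, ambiguous reads and reads not uniquely aligned. A smaller table of 15308 transcripts held the same counts (443932 of 443932 compared values identical), so the larger files were used. Reads that could belong to several transcripts of a gene appear as ambiguous in such counting, and 306 of the 506 genes listed with several transcripts (60.5%) had no tested transcript, against 26.5% of the 15732 genes with 1 transcript.

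Accessions were paired with symbols through a RefSeq gene table of a later rat assembly, used for names only. Of the transcripts, 17090 matched a symbol (16238 genes) and 1002 did not, which held 4.56% of the counts. No gene coordinates or sequences were at hand for the build the authors used, so positions are not given and no check of GC content or length was made.

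Counts were analysed in R 4.3.3 with edgeR 4.0.16. Transcripts were kept by filterByExpr on the 6 groups (minimum count 10, minimum total count 15), which left 12556, and libraries were scaled by TMM (factors between 0.974 and 1.061). A quasi-likelihood model with 6 group means and no covariates was fitted to all 29 libraries, and 14 contrasts were tested two-sided, with Benjamini-Hochberg adjusted p under 0.05 within each contrast as the threshold. They were the 3 comparisons of arms (weeks averaged, week 5, week 11), week 11 against week 5 in each arm, and the difference between the weeks of vehicle against sham and of NT3 against vehicle. Groups of 4 or 5 share the estimate of spread, and the common biological coefficient of variation was 0.185. Log2 CPM values used a prior count of 2, and the principal components were computed on them.

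For genes, the rule fixed before the data were examined named the highest and lowest log2 fold changes among called genes of at least 1 CPM (up to 10 each way for averaged contrasts, up to 5 for the others), or, where no gene was called, the 5 smallest p. It added up to 4 called members per gene list, and in every case a fixed set that held Ntf3, Ntrk2, Ntrk3, Ngfr, Pvalb and Atf3. The text names fewer than the rule allows, and some genes that the rule names are not reported here. Members of lists given as examples, Kcna2 in NT3 against vehicle and the brain genes of rat 27 were chosen after their values were seen.

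The 33 gene lists, written before the data were examined, covered neuron types, glia, immune and connective tissue cells, contaminating tissues and pathways. Each was tested by camera of limma 3.58.1 with a correlation preset at 0.01, Benjamini-Hochberg adjusted over the lists of a contrast, and again with the correlation estimated. Fry, which tests whether the genes of a set move, on balance, one way without comparing them with other genes, was run beside it. Counts adjusted over the list alone use the p-values of its members only. After the values were seen, 4 lists were also tested through their mean log2 CPM per library by exact permutation, two-sided, over 36 comparisons, where the smallest p that 126 or 252 splits allow was 0.00794, and their changes over time by 100000 permutations within weeks or arms.

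Each count was repeated with DESeq2 1.42.0, with limma voom with quality weights, with DESeq2 size factors in edgeR, without the filter, with the smaller table, with only the groups of the contrast in the fit, and without each library in turn. After the data were seen, 3 settings were added: the share of reads outside annotated features as a covariate, all libraries but rats 8 and 27, and both together. For each contrast 100 splits of the libraries, the real one included, were fitted in the same way. The correlations across genes were compared with 100 regroupings.

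The pipeline was tested on simulated data with 50 transcripts changed at each of several folds. For NT3 against vehicle edgeR recovered 20% of those changed 1.25-fold, 78% at 1.5-fold and 100% at 2-fold, with 5 false calls. For week 11 against week 5 in vehicle rats it recovered 10%, 44% and 86%, and 96% at 3-fold, with 6 false calls, and for vehicle against sham at week 5 it recovered 0%, 32%, 80% and 96%, with 9 false calls. A simulated list of 22 transcripts raised together was found by camera with either correlation, and 0 of the 32 other lists were called. Simulated transcripts varied independently, unlike the real ones.

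Depth was 9555685 to 22773108 assigned reads per library, with between 13749 and 14243 transcripts detected. An exact (Clopper-Pearson) 95% binomial interval is given for the share of the pooled reads of forebrain transcription factors in 1 library, and it covers counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.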

Results

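RNA was sequenced from whole dorsal root ganglia of cervical levels C6 to C8, the clusters of sensory neurons that serve the forelimb, in elderly Lister Hooded rats. The animals belonged to 3 arms: rats without a stroke (called sham in the sample labels and naïve in the series text), rats with a unilateral cortical stroke and vehicle infused under the skin, and rats with the same stroke and neurotrophin-3 (NT3) infused under the skin. Ganglia were taken at week 5 or week 11, which gave 6 groups and 29 libraries, each from another rat. The week 5 sham group held 4 libraries and each other group held 5. Reads assigned to annotated transcripts numbered between 16703574 and 22773108 per library in 28 libraries, and 9555685 in week 11 vehicle rat 27. Of the 18092 RefSeq transcripts counted, 12556 were tested. Genes are named by symbol with their RefSeq transcript where their values are given in full, expression is in library-scaled counts (CPM), and changes are log2 fold changes with their standard error (SE).

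Transcripts of Ntrk2 and Ngfr, 2 receptors of neurotrophins, were at similar levels in the 3 arms. The transcript NM_001163168 of Ntrk2, the receptor of brain-derived neurotrophic factor, which held 166634 of the 187554 reads counted for the 2 transcripts of this gene, was at 291 ± 50.7 CPM (SD, n = 9) in sham, 306 ± 34.8 (SD, n = 10) in vehicle and 325 ± 24.6 (SD, n = 10) in NT3 libraries, both weeks together. Ngfr (NM_012610), the low-affinity receptor of all neurotrophins, was at 937 ± 170, 848 ± 117 and 886 ± 105 CPM. Ntrk3, the main receptor of NT3, could not be assessed, because its 3 transcripts in the files held 1 read over all libraries, and the 4 transcripts of Ntf3, the gene of NT3 itself, held 0. Genes listed with several transcripts were under-counted in these files: a gene with several transcripts had a median of 82.5 reads over all libraries (506 genes), and a gene with 1 transcript had 7102.5 (15732 genes). Values of such genes, Ntrk2 included, are therefore no measure of their full expression.

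The first comparison, vehicle against sham, set stroke rats that received no NT3 against rats without a stroke. An infusion is described for the stroke rats only, so an effect of the stroke cannot be told apart from one of the vehicle infusion. The list differences in this paragraph were small, none of the 6 passed with an estimated correlation, and sham libraries also had a lower share of reads outside annotated features, which went with the main axis of variation between libraries (described below). With camera's preset correlation, voltage-gated channel genes of sensory neurons were slightly higher in vehicle rats (median log2 fold change 0.14, 28 of 41 members positive), as were axon guidance genes (0.18, 31 of 43) and synapse and vesicle genes (0.19, 30 of 43). Unfolded protein response genes were lower (median -0.16, 4 of 18 positive), as were genes of the respiratory chain (-0.14, 4 of 68) and ribosomal proteins (-0.12, 0 of 72). The respiratory chain difference was small at week 5 (mean log2 CPM 7 ± 0.12 in vehicle, 7.05 ± 0.14 in sham libraries). At week 11 it was 6.97 ± 0.05 against 7.15 ± 0.25, with sham libraries from 6.96 to 7.49. Ribosomal proteins were at 7.05 ± 0.14 and 7.13 ± 0.13 at week 5, and 7.11 ± 0.11 and 7.28 ± 0.25 at week 11. Kcna2 (NM_012970), a potassium channel subunit found along myelinated axons, was at 115 ± 30.2 CPM (SD, n = 10) in vehicle and 65.2 ± 20.5 (SD, n = 9) in sham libraries, a log2 difference of 0.81 (SE 0.18; edgeR adjusted p = 0.269). The netrin receptor genes Dcc and Unc5d differed by 0.79 (SE 0.22) and 0.82 (SE 0.24), and Syt1, the calcium sensor of synaptic vesicles, by 0.36 (SE 0.12). Creld2, Chac1 and Sdf2l1, which act in or downstream of the stress response of the endoplasmic reticulum, differed by -0.44 (SE 0.14), -0.35 (SE 0.11) and -0.40 (SE 0.14).

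In vehicle against sham with the weeks averaged edgeR called 0 of 12556 transcripts, with 2118 at an unadjusted p under 0.05, DESeq2 called 0 and limma voom with quality weights called 36. Adjusted over the list alone, 1 channel gene (Kcna2, adjusted p = 0.00639), 2 axon guidance genes (Dcc and Unc5d) and 5 unfolded protein response genes passed. The 6 lists named above passed camera with its preset correlation, with adjusted p between 1.22e-09 (respiratory chain) and 0.00463 (axon guidance), and none of them passed with an estimated correlation (adjusted p = 0.813 with an estimated correlation for each). With the share of reads outside annotated features as a covariate, a setting chosen after the data were seen, 5 of the 6 still passed with the preset correlation, and ribosomal proteins, vehicle vs sham, weeks averaged had an adjusted p of 0.0532. The other genes with the smallest p were Slc26a6 (NM_001143817; -0.26, SE 0.06), Elovl1 (NM_001044275; -0.24, SE 0.05), Calhm2 (NM_001008306; -0.39, SE 0.09) and the unnamed transcript NM_001107939 (0.63, SE 0.14), each with an adjusted p of 0.269. Proprioceptor markers (median -0.02; adjusted p = 0.686) and Pvalb (NM_022499), a marker of proprioceptors at 163 ± 14.7 against 176 ± 32.9 CPM, did not differ by the test, nor did Atf3 (NM_012912), a gene induced by axon injury, at 17.6 ± 1.75 against 21.5 ± 3.7 CPM (-0.29, SE 0.14; adjusted p = 0.294).

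Within week 5, macrophage, antigen presentation and fibroblast genes of vehicle rats lay below those of sham rats. The mean log2 CPM of macrophage markers was 2.87 ± 0.18 (SD, n = 5) in vehicle and 3.41 ± 0.23 (SD, n = 4) in sham libraries, that of antigen presentation genes was 4.47 ± 0.08 and 4.82 ± 0.16, and that of fibroblast and matrix genes was 5.74 ± 0.07 and 6.01 ± 0.15. In each of these 3 lists all 5 vehicle libraries lay below all 4 sham libraries (exact permutation p = 0.00794, two-sided, adjusted p = 0.0318 over 36 such tests, which were chosen after the values were seen). Inflammatory genes, the other list tested in this way, did not pass (-0.16; exact permutation p = 0.0714, adjusted p = 0.198), and interferon-stimulated genes were at 3.96 ± 0.05 and 4.03 ± 0.1. Clec10a (NM_022393), a lectin of tissue macrophages, was at 4 ± 0.612 against 8.16 ± 1.15 CPM (-1.03, SE 0.23), and the secreted protein gene Crispld2 (NM_138518) at 45.8 ± 5.69 against 78 ± 11.8 CPM (-0.77, SE 0.17). Fam180a (NM_001108621) was at 2.85 ± 0.736 against 6.66 ± 2.03 CPM (-1.23, SE 0.25). The glutathione transferase gene Gsta6 (NM_001024361) was at 12.6 ± 3.58 against 0.745 ± 0.154 CPM, but single libraries of the week 11 sham group also ranged from 0.531 to 7.58 CPM. Some neuronal lists lay the other way in the same libraries: voltage-gated channels were at 6.37 ± 0.09 (SD, n = 5) in vehicle and 6.1 ± 0.14 (SD, n = 4) in sham libraries, without overlap, and synapse and vesicle genes at 6.19 ± 0.14 and 5.87 ± 0.22. Others did not, such as peptidergic nociceptor markers (6.01 ± 0.06 and 6.07 ± 0.05) and proprioceptor markers (5.73 ± 0.17 and 5.67 ± 0.07). Myelinating Schwann cell markers were at 6.68 ± 0.08 and 6.81 ± 0.02. These groups also differed in the mean of the first principal component, 8.8 in vehicle and -17.1 in sham libraries (SD 18.01 and 17.4).

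At week 5 edgeR called 0 transcripts in vehicle against sham, with 1052 at an unadjusted p under 0.05 and a smallest adjusted p of 0.296, while DESeq2 called 10 and limma voom with quality weights called 1079. Camera with the preset correlation placed macrophage markers lower (median -0.57, 1 of 22 positive; adjusted p = 3.11e-10, and adjusted p = 0.384 with an estimated correlation), with 3 members lower adjusted over the list alone. Of the 33 lists, 13 passed in this way, 10 lower and 3 higher, and 0 passed with an estimated correlation. Camera with the preset correlation also placed fibroblast and matrix genes lower (-0.28; adjusted p = 0.000111, and 0.384 with an estimated correlation) and antigen presentation genes lower (-0.27; adjusted p = 0.00331, and 0.645 with an estimated correlation). At week 11 the vehicle and sham libraries did not differ in these 3 scores (exact permutation p = 0.437, 0.706 and 0.706 for macrophage, antigen presentation and fibroblast genes). There edgeR called 0 transcripts with 1228 at an unadjusted p under 0.05, DESeq2 called 0 and limma voom called 2. The genes with the smallest p at week 11 included the brain genes Mobp (NM_012720; 18.6 ± 39.5 against 0.952 ± 0.257 CPM) and Nrgn (NM_024140; 13.7 ± 28.6 against 0.989 ± 0.195 CPM), whose means rested on rat 27.

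**Figure D1:**
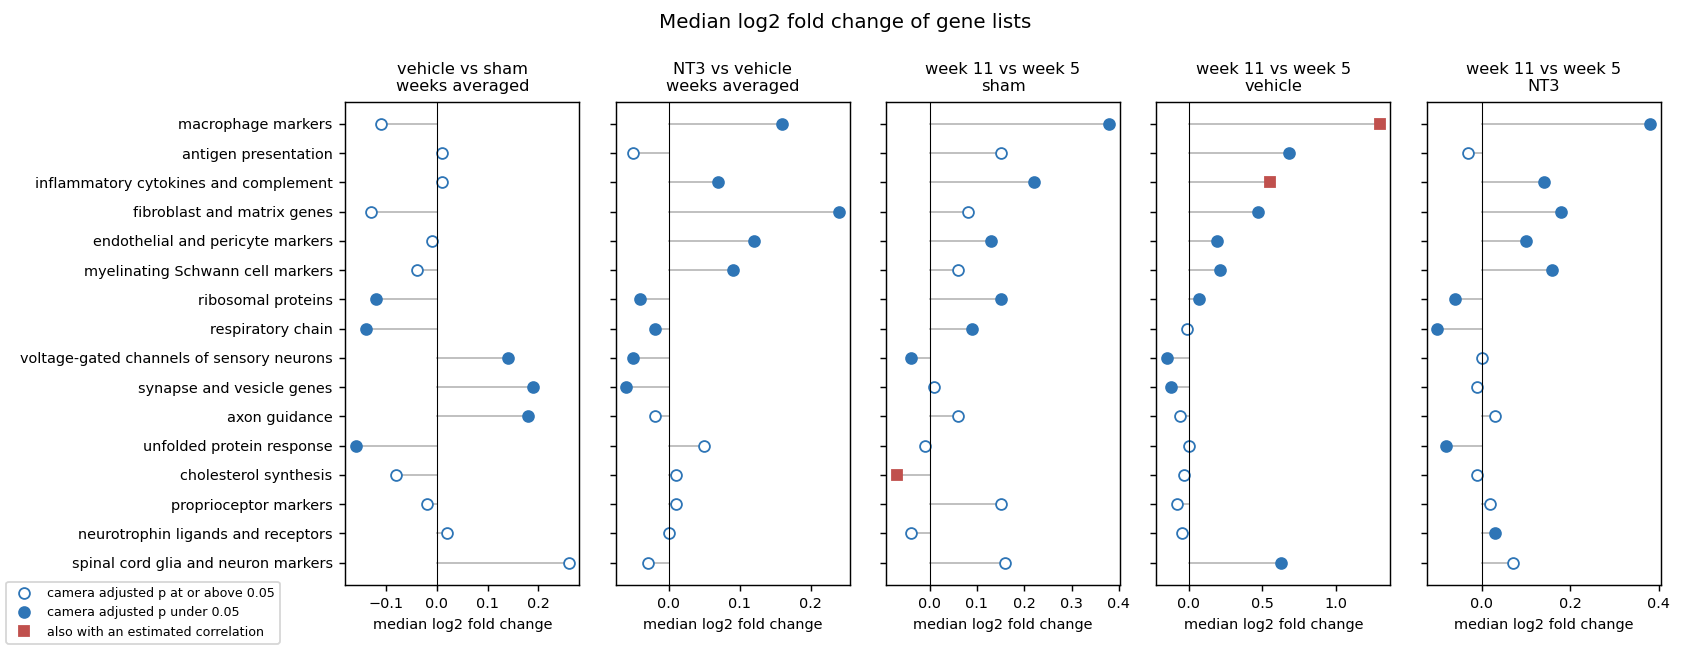
Median log2 fold change (horizontal axis, with its own scale in each panel) of 16 gene lists in 5 comparisons. Open circles are lists that did not pass camera with the preset correlation, filled circles are lists that did, and red squares are lists that also passed with an estimated correlation, which held for macrophage markers (1.30) and inflammatory genes (0.55) in vehicle rats and cholesterol synthesis (-0.07) in sham rats.

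NT3 against vehicle, the comparison on what NT3 changed after a stroke, showed slightly higher connective tissue and vessel genes in NT3 rats by camera with the preset correlation. Of the 33 lists, 12 passed in this way, 6 higher and 6 lower, and no list passed with an estimated correlation. Fibroblast and matrix genes had a median log2 fold change of 0.24, with 18 of 18 members positive. Their mean log2 CPM differed by 0.35 at week 5 and by only 0.1 at week 11 (exact permutation p = 0.00794 and 0.524). Bgn and Mfap5, which encode proteins of the extracellular matrix, differed by 0.32 (SE 0.10) and 0.28 (SE 0.09). Endothelial and pericyte markers had a median of 0.12, with 22 of 22 positive, among them the cell adhesion gene Esam (0.22, SE 0.07) and Vwf, the gene of von Willebrand factor (0.28, SE 0.10). Myelinating Schwann cell markers (median 0.09, 17 of 19 positive) and macrophage markers (0.16, 21 of 22) were also higher, the latter from week 5 (0.55 in mean log2 CPM) and not from week 11 (-0.2), while antigen presentation genes had a median of -0.05. Voltage-gated channel genes lay the other way (median -0.05, 6 of 41 positive), and Kcna2 was at 77.7 ± 16.1 CPM (SD, n = 10) in NT3 libraries against 115 ± 30.2 (SD, n = 10) in vehicle libraries (-0.57, SE 0.18; adjusted p = 1).

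For NT3 against vehicle with the weeks averaged edgeR called 0 of 12556 transcripts, with 417 at an unadjusted p under 0.05, which is 3.3% of those tested, and DESeq2 and limma voom with quality weights called 0 each. In data simulated from this comparison edgeR recovered 78% of transcripts changed 1.5-fold and 100% of those changed 2-fold. The simulated transcripts varied independently and lacked the main axis of variation between libraries. These shares therefore do not give the power in the real data, and changes of such size are not excluded. Adjusted over the list alone, Bgn and Mfap5 passed (adjusted p = 0.0418 each). With the preset correlation camera gave adjusted p = 5.28e-13 for fibroblast and matrix genes and 0.118 with an estimated correlation. Endothelial and pericyte markers had 2.31e-07, and adjusted p = 0.374 with an estimated correlation. Schwann cell markers had 0.000214, macrophage markers 3.91e-05 and channels 0.00057, each with adjusted p = 0.602 with an estimated correlation. The genes with the smallest p included Ly6g5b (NM_001001934; 0.97, SE 0.21), the neuronal non-coding RNA Bc1 (NR_036653; -0.82, SE 0.20) and Efcab2 (NM_001105977; -0.38, SE 0.10), each with an adjusted p of 1. Proprioceptor markers (median 0.01; adjusted p = 0.931), neurotrophin ligands and receptors (0.00; 0.931) and Pvalb (0.02, SE 0.08) did not differ by the test, and Atf3 was at 22.5 ± 6.9 against 17.6 ± 1.75 CPM (0.36, SE 0.13; adjusted p = 1).

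At week 5 the macrophage, antigen presentation and fibroblast scores of NT3 rats lay at the sham level and above that of vehicle rats. All 5 NT3 libraries lay above all 5 vehicle libraries in each of the 3 lists, by 0.55, 0.35 and 0.35 log2 CPM (exact permutation p = 0.00794, adjusted p = 0.0318), and the NT3 and sham scores differed by 0.01, 0.01 and 0.09 (exact p = 0.952, 0.952 and 0.405). The differences of week 5 vehicle rats from sham, NT3 and week 11 vehicle rats rest on the same 5 libraries. They are not independent results, and a return to the sham level cannot be told apart from 5 low vehicle libraries. Fam180a (1.14, SE 0.24), Crispld2 (0.71, SE 0.16), Col15a1 (NM_001100535; 0.63, SE 0.14), a collagen of basement membranes, and Gfpt2 (NM_001002819; 0.57, SE 0.12) had the smallest p, each with an adjusted p of 0.382. Camera placed macrophage markers higher (median 0.57, 22 of 22 positive; adjusted p = 4.36e-18, and adjusted p = 0.253 with an estimated correlation), with 6 members higher adjusted over the list alone. Fibroblast and matrix genes were higher too (0.38; adjusted p = 3.66e-12, and 0.167 with an estimated correlation), with 9 members higher adjusted over the list alone. In the same libraries voltage-gated channels were at 6.2 ± 0.06 log2 CPM in NT3 and 6.37 ± 0.09 in vehicle rats. Synapse and vesicle genes were at 6.04 ± 0.14 and 6.19 ± 0.14, endothelial and pericyte markers at 4.73 ± 0.17 and 4.55 ± 0.16. Schwann cell markers were at 6.77 ± 0.1 and 6.68 ± 0.08, and proprioceptor markers at 5.73 in both. EdgeR called 0 transcripts at week 5 with 626 at an unadjusted p under 0.05, DESeq2 called 0 and limma voom called 36. At week 11 the macrophage, antigen presentation and fibroblast scores did not differ (exact p = 0.563, 0.333 and 0.524), and edgeR called 0 with 191 at an unadjusted p under 0.05, as did DESeq2 and limma voom with 0 each.

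**Figure D2:**
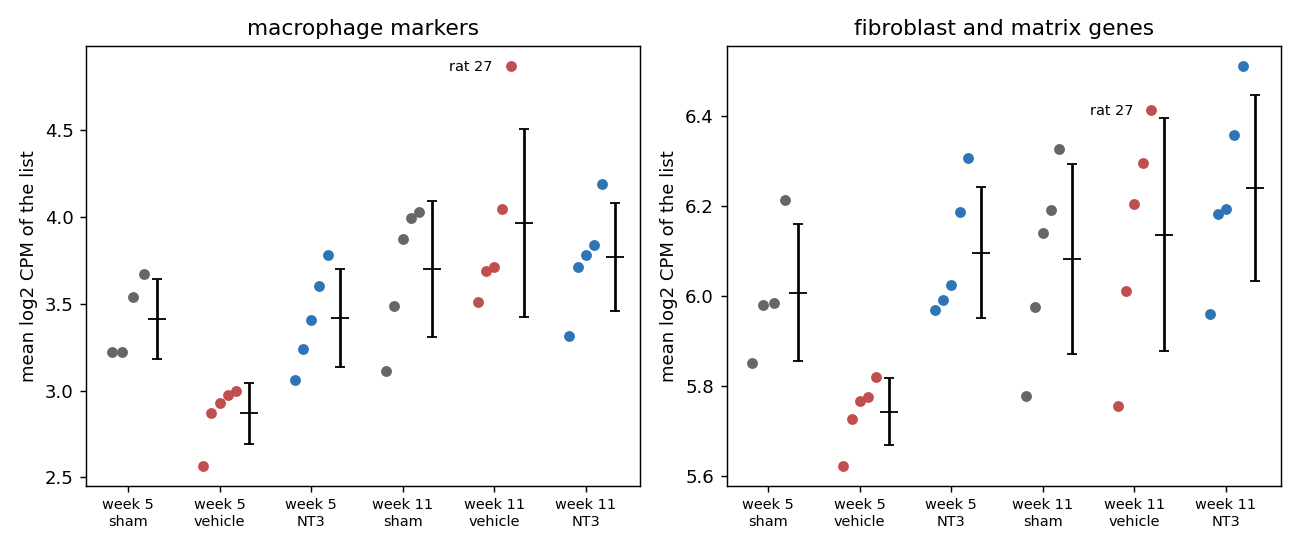
Mean log2 CPM of the members of 2 gene lists, macrophage markers (left) and fibroblast and matrix genes (right), per library. Each point is 1 rat, and the bars show the mean and SD of each group of 4 or 5. The 5 week 5 vehicle libraries lay below all week 5 sham and NT3 libraries in both lists.

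NT3 against sham compared treated stroke rats with rats without a stroke. Here too the list differences were small, none passed with an estimated correlation, and the share of reads outside annotated features was lower in sham libraries. With the preset correlation, axon guidance genes were slightly higher in NT3 rats (median 0.18, 32 of 43 positive), as were endothelial and pericyte markers (0.14, 18 of 22). Genes of the respiratory chain (-0.16, 2 of 68 positive), ribosomal proteins (-0.15, 1 of 72) and the unfolded protein response (-0.11, 4 of 18) were lower. The first 2 differed mainly at week 11, where sham libraries were spread out. The respiratory chain was at a mean log2 CPM of 7 ± 0.05 in NT3 and 7.05 ± 0.14 in sham libraries at week 5, and 6.91 ± 0.06 and 7.15 ± 0.25 at week 11. Ribosomal proteins were at 7.08 ± 0.06 and 7.13 ± 0.13, and 7.04 ± 0.06 and 7.28 ± 0.25. Pex11a (NM_053487), a peroxisome gene, was at 23.7 ± 5.72 CPM (SD, n = 10) in NT3 and 15.8 ± 3.21 (SD, n = 9) in sham libraries (0.57, SE 0.14), and Rspo3 (NM_001100990), an enhancer of Wnt signalling, at 0.722 ± 0.242 and 0.37 ± 0.101 CPM (0.93, SE 0.24). Ift27 (NM_001130495), a gene of transport in cilia, was at 19.1 ± 1.11 and 23.5 ± 4.4 CPM (-0.29, SE 0.08). These 3 genes had an adjusted p of 0.461.

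Over the averaged weeks edgeR called 0 transcripts in NT3 against sham, with 1331 at an unadjusted p under 0.05, and DESeq2 and limma voom with quality weights called 0 each. The 5 lists passed camera with the preset correlation (adjusted p from 5.32e-18 for the respiratory chain to 0.0206 for the unfolded protein response) and had an adjusted p of 0.73 or 0.74 with an estimated correlation. With the share as a covariate 4 of the 5 still passed with the preset correlation, and unfolded protein response, NT3 vs sham, weeks averaged had an adjusted p of 0.0666. At week 5 edgeR called 0 with 301 at an unadjusted p under 0.05, the kinase gene Akt2 (NM_017093; 43.4 ± 0.939 against 55.1 ± 2.44 CPM; -0.34, SE 0.09; adjusted p = 0.81) being among the smallest p, and the other tools called 0 each. At week 11 edgeR called 0 with 1145 at an unadjusted p under 0.05, DESeq2 called 0 and limma voom called 4.

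Macrophage and inflammatory genes were higher at week 11 than at week 5 in the ganglia of vehicle rats. The week 5 vehicle libraries had low macrophage scores, below all week 5 sham and NT3 libraries. The week 11 vehicle scores did not differ from sham or NT3 (exact permutation p = 0.437 and 0.563). Most calls of single genes were lost without week 11 vehicle rat 27, whose library held brain transcripts (described below). Without it, 1 macrophage marker and 0 inflammatory or antigen presentation genes were called, as was so without week 5 vehicle rat 1. The list medians without rat 27 were 0.95, 0.41 and 0.26, against 1.30, 0.55 and 0.68 with all libraries. Of the 22 macrophage markers tested, 15 were called higher, with a list median of 1.30, and all 22 passed adjusted over the list alone. Tyrobp (NM_212525), a signalling adaptor of myeloid cells, went from 3.93 ± 0.365 to 11.3 ± 5.15 CPM (SD, n = 5 each; 1.50, SE 0.22; adjusted p = 0.00459), the folate receptor gene Folr2 (NM_001106283) from 2.18 ± 0.506 to 5.32 ± 1.19 (1.28, SE 0.22), Clec10a from 4 ± 0.612 to 9.31 ± 3.86 (1.20, SE 0.22) and the Fc receptor subunit gene Fcer1g (NM_001131001) from 7.6 ± 2.25 to 22.1 ± 12.6 (1.52, SE 0.28). Of the inflammatory cytokine and complement genes 4 of 19 were called higher: C3 (NM_016994; 1.96, SE 0.43), Il1b (NM_031512; 1.34, SE 0.29), Tgfb1 (NM_021578; 0.97, SE 0.18) and C2 (NM_172222; 0.93, SE 0.22). Of the 14 antigen presentation genes 4 were called higher, all of the class II major histocompatibility pathway: RT1-Da (NM_001008847; 2.53, SE 0.50), Cd74 (NM_013069; 2.49, SE 0.47), RT1-Ba (NM_001008831; 1.95, SE 0.39) and RT1-Bb (NM_001004084; 1.79, SE 0.35). In the same libraries the mean log2 CPM of voltage-gated channels went from 6.37 ± 0.09 to 6.22 ± 0.12. Synapse and vesicle genes went from 6.19 ± 0.14 to 6.03 ± 0.2, and endothelial and pericyte markers from 4.55 ± 0.16 to 4.72 ± 0.1. Proprioceptor markers were at 5.73 ± 0.17 and 5.71 ± 0.15.

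In all, edgeR called 106 transcripts in week 11 against week 5 in vehicle rats, 104 higher and 2 lower, with 1107 at an unadjusted p under 0.05. The others named by the rule were Fcgr3a (NM_207603; 2.28, SE 0.47), Cd4 (NM_012705; 1.34, SE 0.26), the MAPK phosphatase gene Dusp6 (NM_053883; 0.66, SE 0.15), and the 2 lower genes, the cilium gene Ccdc40 (NM_001134688; -0.65, SE 0.14) and the mitochondrial enzyme gene Dmgdh (NM_139102; -0.54, SE 0.13). Camera placed macrophage markers higher (adjusted p = 3.35e-41, and adjusted p = 0.02 with an estimated correlation), as it did inflammatory genes (median 0.55; 2.27e-12, and 0.0234 with an estimated correlation). The test with an estimated correlation was not run without rat 27. Antigen presentation genes (0.68; 6.01e-10) and fibroblast and matrix genes (0.47, 0 called, 11 adjusted over the list alone; 1.27e-09) passed with the preset correlation but had adjusted p = 0.191 and 0.139 with an estimated correlation. The median of antigen presentation genes was 0.26 without rat 27 (10 of 14 positive, 0 called). Without rat 27 edgeR called 1 transcript, Tyrobp (1.20; adjusted p = 0.00661), and without week 5 vehicle rat 1 it also called Tyrobp alone (1.45; adjusted p = 0.0281). Without rat 27, 103 of the 104 higher transcripts were still positive (median 0.95, against 1.26). They had been chosen as higher with the remaining libraries in the fit, so their sign is no independent support. Of these 104, 94 were also positive in sham rats (median 0.32) and 95 in NT3 rats (0.26). Without rat 27, Cd74 and RT1-Da were at 1.29 and 1.16, C3 at 1.17, Fcgr3a at 1.43, RT1-Ba at 1.03, RT1-Bb at 1.06 and C2 at 0.52. Mobp, called at 4.15 with all libraries, was at -0.07. The call count was 0 when only the 2 vehicle groups were fitted.

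In the mean log2 CPM per library, macrophage markers were higher at week 11 in all 5 vehicle rats than in any week 5 vehicle rat, by 1.10 (exact permutation p = 0.00794, adjusted p = 0.0318), and by 0.87 without rat 27 (exact p = 0.00794). Antigen presentation genes differed by 0.70, and by 0.40 without rat 27, with the same exact p. In the sham and NT3 arms combined, macrophage markers were 0.32 higher at week 11 (permutation p = 0.0416). The change in vehicle rats exceeded that of the other arms by 0.78 (permutation p = 0.00601, adjusted p = 0.012 over 4 lists), and by 0.55 without rat 27 (permutation p = 0.0316, adjusted p = 0.0978). For antigen presentation the excess was 0.64 (permutation p = 0.00586, adjusted p = 0.012), and 0.34 without rat 27 (permutation p = 0.0489, adjusted p = 0.0978). It was 0.34 for inflammatory genes, which were also 0.21 higher at week 11 in the sham and NT3 arms (permutation p = 0.0276), and this excess did not pass (permutation p = 0.0394, adjusted p = 0.0525; permutation p = 0.17 without rat 27). For fibroblast and matrix genes it was 0.29 (permutation p = 0.0775, adjusted p = 0.0775). These per-library tests were chosen after the values were seen, and other rats were sampled at each week.

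In sham rats, cholesterol synthesis genes fell between week 5 and week 11 as a list (median -0.07, 4 of 25 positive; adjusted p = 2.78e-07, and adjusted p = 0.0114 with an estimated correlation). Sqle, an enzyme of the pathway, was at -0.23 (SE 0.07; adjusted p = 0.0605 over the list alone), and no member was called. EdgeR called 0 transcripts in this comparison with 468 at an unadjusted p under 0.05, DESeq2 called 0 and limma voom with quality weights called 2209. Without rats 8 and 27 and with the share of reads outside annotated features as a covariate, edgeR called 1304 in week 11 vs week 5, sham, but 0 with either change alone. Macrophage markers were higher (median 0.38, 18 of 22 positive; adjusted p = 0.000103, and 0.617 with an estimated correlation). In NT3 rats edgeR, DESeq2 and limma voom called 0 transcripts, with 198 at an unadjusted p under 0.05 by edgeR. There macrophage markers (median 0.38, 22 of 22 positive) and myelinating Schwann cell markers (0.16, 17 of 19) passed camera (adjusted p = 1.26e-10 and 1.51e-10) and had adjusted p = 0.347 and 0.217 with an estimated correlation.

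Whether the effect of an arm differed between the weeks was tested directly. For vehicle against sham, macrophage markers had a median difference of 0.91 (week 11 minus week 5; 22 of 22 positive, 10 higher adjusted over the list alone), and Clec10a one of 1.53 (SE 0.31; adjusted p = 0.456). For NT3 against vehicle the median was -0.88 (0 of 22 positive, 10 lower adjusted over the list alone), with Clec10a at -1.16 (SE 0.30; adjusted p = 1) and RT1-Da at -2.63 (SE 0.68; adjusted p = 1). Without rat 27 the value of Clec10a in difference between weeks of NT3 vs vehicle was -0.897, and that of RT1-Da in difference between weeks of NT3 vs vehicle was -1.261. EdgeR called 0 transcripts in each, with 384 and 378 at an unadjusted p under 0.05. DESeq2 called 1 and 0, and limma voom with quality weights called 1 and 0. The macrophage lists passed camera with the preset correlation (adjusted p = 1.14e-21 and 3.12e-20), and had adjusted p = 0.287 and 0.323 with an estimated correlation.

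Across the 12556 tested transcripts, which are not independent replicates, the week 5 and week 11 fold changes correlated with Pearson r = 0.25 for vehicle against sham, -0.03 for NT3 against vehicle and 0.33 for NT3 against sham. The sign rested on few libraries: the agreement of the 2 weeks: NT3 vs sham was -0.125 without rat 8 and -0.207 with the share of reads outside annotated features as a covariate, and the agreement of the 2 weeks: vehicle vs sham was -0.01 and -0.06 in these settings. On the log2 CPM scale the values were 0.38, -0.05 and 0.45, and 100 random regroupings of the libraries within each week gave a mean of 0.01, 0.05 and 0.04 with an SD of 0.34, 0.33 and 0.35. The fold changes of NT3 against vehicle and of vehicle against sham correlated with r = -0.56. Both use the vehicle libraries, and regroupings without any effect gave a mean of -0.45 on the log2 CPM scale, where the observed value was -0.53 (SD of the regroupings 0.30). With the vehicle libraries split so that the 2 contrasts shared none, the mean over 100 splits was -0.12, and 24 splits were positive.

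Libraries also differed along an axis that the groups did not explain. The first principal component, with 44% of the variance of log2 CPM, followed the share of reads outside annotated features, which ranged from 21.05% to 28.55% (Pearson r = 0.88, Spearman rho = 0.92, 29 libraries; permutation p = 1e-05, the smallest that 100000 permutations can give). The correlation was 0.93 without rats 8 and 11 of the week 11 sham group, the 2 farthest from the median share, and 0.91 within groups. Genes at one end included Cep290, Smc4 and Ift74, and at the other end Tmem158, Nccrp1 and Pfn2. The mean share was 25.85% in week 5 sham, 27.14% in week 5 vehicle and 26.98% in week 5 NT3 libraries, and 24.71%, 26.26% and 26.69% at week 11. With the share as a covariate, 744 transcripts (5.9%) had an unadjusted p under 0.05 in vehicle vs sham, weeks averaged, in place of 2118 (16.9%).

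**Figure D3:**
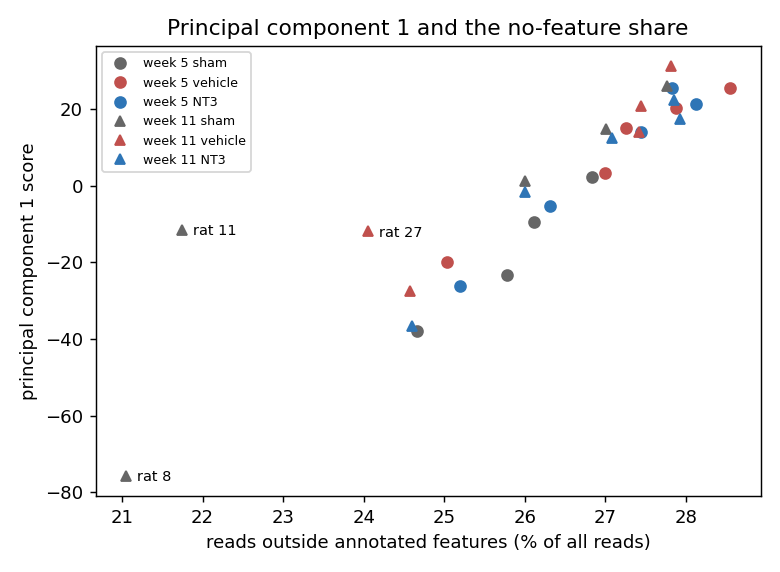
First principal component of log2 CPM (vertical axis) against the percent of reads outside annotated features (horizontal axis). Each point is 1 of 29 libraries, coloured by arm, with circles for week 5 and triangles for week 11. The points rise from lower left to upper right (r = 0.88), with rat 11 above the line of the others.

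The library of week 11 vehicle rat 27 held transcripts of brain genes that were near 0 elsewhere. Mobp, a gene of oligodendrocyte myelin, was at 89.4 CPM in rat 27 and at most 1.39 CPM in the other 28 libraries, and Nrgn, a gene of forebrain neurons, at 64.9 and at most 2.65 CPM. Neurod6, a transcription factor gene of cortical neurons, had 145 reads in rat 27 of 149 in all libraries, and Neurod2 had 32 of 32. Of its reads 37.17% did not align uniquely, against 16.32% to 19.32% in the other libraries. Markers of spinal cord glia and neurons had a mean log2 CPM of 3.78 in rat 27 and between 2.11 and 2.41 in the other week 11 vehicle libraries. This library entered each comparison that uses week 11 vehicle rats.

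**Figure D4:**
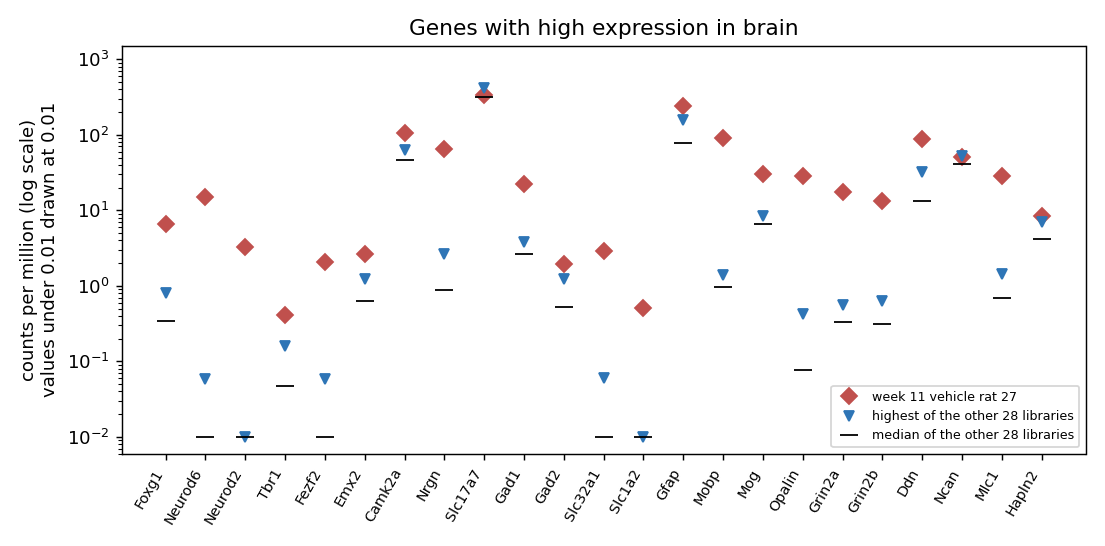
Expression in CPM (vertical log axis, with values under 0.01 drawn at 0.01) of 23 genes with high expression in brain. Diamonds are week 11 vehicle rat 27, triangles the highest and dashes the median of the other 28 libraries. Mobp was at 89.4 CPM in rat 27 and at most 1.39 CPM elsewhere.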

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

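The tests of a library property behind the small p-values, of a lasting stroke effect, of rat 27 and of time behind the macrophage markers, of brain or spinal cord RNA in rat 27, and of the list scores per library were chosen after the results were seen. The bounds for rat 27 as the whole cause and for spinal cord were also set after their values were known. The test for a mislabelled library and the counts of other splits were fixed before their results were seen.

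In vehicle against sham 16.9% of transcripts had an unadjusted p under 0.05 over the averaged weeks, though none was called by edgeR. With the share of reads outside annotated features as a covariate the figure was 5.9%, so a library property that moves with this share, such as RNA quality or library preparation, is a candidate explanation. The mean share was itself higher in vehicle than in sham libraries (27.14% against 25.85% at week 5, 26.26% against 24.71% at week 11). The covariate can therefore also take up part of a true difference between the arms, and the fall cannot tell these apart. A lasting effect of the stroke stayed open, because 18 of 100 regroupings of the libraries gave fold changes that agreed as well between the weeks as the real arms did. These arms also cannot separate the stroke from the vehicle infusion. Of 100 splits of the libraries 9 gave as many small p-values (2118, with 3836 as the highest of the others), and 9 did so for NT3 against sham (1331, with 5201), so chance cannot be excluded for either. Splits that gave far more than the real one point to a structure among the samples other than the arms.

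The difference of macrophage markers between week 5 and week 11 was larger in vehicle rats than in the sham and NT3 arms. The excess was 0.78 log2 CPM (permutation p = 0.00601), and that of antigen presentation genes was 0.64. Without rat 27 the excess was 0.55 and 0.34 (permutation p = 0.0316 and 0.0489, adjusted p = 0.0978 for each). Brain RNA in rat 27 as the whole cause was argued against, since without that rat the scores of vehicle rats still differed between the weeks by 0.87 and 0.4 (exact permutation p = 0.00794 each), although the 4 called antigen presentation genes went from a median of 2.22 to 1.11. A property that moves with the no-feature share was argued against for the macrophage markers by a median of 1.23 with the share as a covariate, against 1.30, and a change over time shared alike by all arms by the permutation p of 0.00601, though less so without rat 27 (permutation p = 0.0316, adjusted p = 0.0978 over 4 lists). Low week 5 vehicle scores enter this change. Macrophage markers of vehicle rats differed from sham by -0.54 at week 5 and by 0.27 at week 11 (exact permutation p = 0.00794 and 0.437). NT3 rats differed from vehicle rats by 0.55 and -0.2 (exact permutation p = 0.00794 and 0.563). Antigen presentation scores of vehicle rats at week 11 did not differ from sham or NT3 either (exact permutation p = 0.706 and 0.333). High week 11 vehicle scores were thus not shown. A change in the number or state of macrophages, differences in dissection and the handling of the 2 weeks stayed open and untested. Of 100 splits of the vehicle libraries, only the real split gave as many as 106 called transcripts (1 of 100, with 1 as the highest of the others). This argues against chance for the count of calls alone. Of the 14 contrasts, however, edgeR called transcripts in this contrast only, and the count went to 1 without rat 27 or without rat 1. For transcripts at an unadjusted p under 0.05, 12 of 100 splits gave as many (1107, with 2768 as the highest of the others). Chance therefore cannot be excluded.

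The library of week 11 vehicle rat 27 stood apart by brain transcripts. RNA from brain tissue may have entered it, since 15 of the 17 listed brain-abundant genes with reads were highest there, among them Mobp, Nrgn and Gfap (237 CPM, against at most 159 elsewhere), while Slc17a7 (340 CPM) and Ncan (51.4 CPM) were within the range of the other libraries, which express them too. Spinal cord left on the ganglia was argued against as the sole source, because 291 of the 884 reads of forebrain transcription factors (32.9%, exact 95% interval 29.8 to 36.1) were in this library, which held 1.77% of the gene counts. A library of another tissue under a wrong label was argued against by ganglion genes, which differed from the other week 11 vehicle libraries by a median of 0.01 log2 CPM (8 genes, from -0.34 to 0.44). The step at which such RNA entered was not tested, and no biological explanation was tested.

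Single libraries far from the others of their group were sought in 432 groups of values, and chance flags about 1 in 20 groups, or 21.6 here, against 35 found; the genes searched were those named in the text, several of them because of rat 27, so an excess over chance is in part a result of that choice. In week 11 vehicle rat 27 these were gene counts of 9.56 M reads (17.77 to 19.3 in the others of its group), reads not uniquely aligned at 37.17% (16.8% to 18.92%), the mean log2 CPM of spinal cord markers at 3.78 (2.11 to 2.41), Mobp at 89.4 CPM and Nrgn at 64.9 CPM. The immune genes of rat 27 were also far above the others: Cd74 at 613 CPM (51.1 to 128), RT1-Da at 169 (13.6 to 27.4), C3 at 160 (17.6 to 53), RT1-Ba at 55.1 (7.93 to 12.9), Cd4 at 48.9 (14.7 to 22), Fcer1g at 44.5 (15.1 to 18.1), RT1-Bb at 22 (3.88 to 6.07), Tyrobp at 20.3 (7.73 to 10.6) and Fcgr3a at 14.8 (2.34 to 3.15). The share not uniquely aligned and the 291 forebrain reads lie in data that the comparisons did not use, where the 28 other libraries had at most 19.32% and 32 such reads, and sham libraries at most 23 of the latter.

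In week 11 NT3 rat 69 the mean log2 CPM was 7.14 for ribosomal proteins (7 to 7.04 in the others), 5.88 for voltage-gated channels (6.24 to 6.28), 5.57 for synapse and vesicle genes (6.12 to 6.15) and 4.84 for axon guidance (5.23 to 5.33). Ntrk2 was at 292 CPM (332 to 339) and Unc5d at 0.517 CPM (1.33 to 1.66) in this library. In week 11 sham rat 8 inflammatory genes were at 2.79 (3.02 to 3.08) and endothelial and pericyte markers at 4.3 (4.7 to 4.85) log2 CPM, and Dmgdh at 7.88 CPM (9.84 to 10.6). In week 11 sham rat 11 Elovl1 was at 149 CPM (117 to 123), and in week 11 vehicle rat 50 Syt1 was at 97.6 CPM (130 to 140).

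At week 5, sham rat 60 had 4.19% ambiguous reads (4.41% to 4.45%) and sham rat 74 had Sqle at 215 CPM (228 to 230). Vehicle rat 82 had unfolded protein response genes at a mean log2 CPM of 6.3 (6.11 to 6.15), and vehicle rat 14 had Syt1 at 206 CPM (147 to 161). NT3 rat 25 had Pvalb at 216 CPM (160 to 170), Bc1 at 5.51 CPM (2.54 to 2.94) and Rspo3 at 1.1 CPM (0.584 to 0.697). NT3 rat 61 had axon guidance genes at 4.96 log2 CPM (5.17 to 5.23), NT3 rat 85 had C3 at 36.4 CPM (18.6 to 23.7) and NT3 rat 56 had Syt1 at 139 CPM (120 to 125).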

How the results depend on the processing

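The share of reads outside annotated features as a covariate and the fits without rats 8 and 27 were chosen after seeing the data, and the other settings were planned. EdgeR with DESeq2 size factors, without the filter and with the smaller table kept every count of called transcripts at 0 or within 1.5 times of 106, and NT3 against vehicle with the weeks averaged, NT3 against sham with the weeks averaged and at week 5, and week 11 against week 5 in NT3 rats stayed at 0 under every setting. DESeq2 called 10 in vehicle vs sham, week 5, 194 in week 11 vs week 5, vehicle, and 1 in the difference between weeks of vehicle vs sham. Limma voom with quality weights called 36 in vehicle vs sham, weeks averaged, 1079 in vehicle vs sham, week 5, 2 in vehicle vs sham, week 11, 36 in NT3 vs vehicle, week 5, 4 in NT3 vs sham, week 11, 2209 in week 11 vs week 5, sham, and 1 in the difference between weeks of vehicle vs sham. With only its groups in the fit, vehicle vs sham, week 5 had 1 call and week 11 vs week 5, vehicle had 0, with fewer libraries to estimate the spread. Without 1 library, week 11 vs week 5, vehicle had between 1 (without rat 27, and without rat 1) and 214 calls (without rat 57), and without rats 8 and 27 it had 24, or 31 with the covariate added, where week 11 vs week 5, sham had 1304. Gene lists passed 128 times by camera with the preset correlation, 3 times with an estimated correlation and 4 times by fry. The agreement of the 2 weeks: vehicle vs sham (0.252) was -0.22 without rats 8 and 27 and with the covariate. The agreement of the 2 weeks: NT3 vs sham (0.328) was between -0.125 (without rat 8) and 0.5 without 1 library, -0.207 with the covariate, -0.128 without rats 8 and 27, and -0.358 with both. Mobp in week 11 vs week 5, vehicle ranged from -0.069 (without rat 27) to 4.471 without 1 library (4.15 with all), and turned to -0.069 without rats 8 and 27 and to -0.04 with the covariate added, since rat 27 held most of its reads. The list call of voltage-gated channels of sensory neurons, week 11 vs week 5, sham (median -0.04, mean 0.01) had an adjusted p between 0.000154 and 0.845 without 1 library and turned its direction without rat 11 (0.845), and that of the respiratory chain, week 11 vs week 5, sham had one between 8e-13 and 0.699 (without rat 8) and turned without rat 11 (0.532), with the covariate (0.867) and with rats 8 and 27 left out as well (0.701). Apart from Mobp, the cause of these changes was not tested. Among the values of single genes and lists, 373 of those recomputed were weaker and 38 stronger. A further 489 changed sign without passing the threshold in either fit, and 7 changed sign with a pass in the main or the other fit. The other 8026 kept their sign and their call. Of 100 splits, limma voom gave as many calls as the real one in 18 for vehicle vs sham, weeks averaged (highest other 4786), 9 at week 5 (2810), 34 at week 11 (6308) and 11 in week 11 vs week 5, sham (5128), so chance cannot be excluded for any of them. Depth of 9555685 to 22773108 reads left 12556 of 18092 transcripts testable, and genes with several transcripts were largely out of reach.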

Other observations

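The lists were fixed and the counts of splits were planned before the data were examined, but which lists to describe here, and Gsta6, were chosen after their values were seen. Several gene groups not yet described for this comparison also differed between week 5 and week 11 in vehicle rats, though not always in vehicle rats alone. The mean log2 CPM of interferon-stimulated genes went from 3.96 to 4.27 in vehicle, 4.03 to 4.26 in sham and 4.09 to 4.24 in NT3 rats. That of myelinating Schwann cell markers went from 6.68 to 6.88 in vehicle, 6.81 to 6.87 in sham and 6.77 to 6.97 in NT3 rats. Interferon-stimulated genes had a median of 0.37 (23 of 27 positive, 4 higher adjusted over the list alone; camera adjusted p = 1.13e-07, and adjusted p = 0.235 with an estimated correlation). Myelinating Schwann cell markers had a median of 0.21 (19 of 19 positive, 6 higher adjusted over the list alone; 2.31e-06, and adjusted p = 0.232 with an estimated correlation). Markers of spinal cord glia and neurons had a median of 0.63 (14 of 14 positive; 2.25e-05, and adjusted p = 0.191 with an estimated correlation), a list in which rat 27 stood apart. In NT3 rats, proliferation genes had a median of 0.13 over the same time (20 of 22 positive; 0.000177, and adjusted p = 0.347 with an estimated correlation) and respiratory chain genes one of -0.10 (5 of 68 positive; 1.18e-13, and adjusted p = 0.473 with an estimated correlation).

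Injury and regeneration genes did not pass in vehicle against sham (median -0.02; camera adjusted p = 0.624) or in NT3 against vehicle (0.00; 0.809), nor did large myelinated neuron markers (0.08; 0.164, and -0.02; 0.39). Peptidergic nociceptor markers did not pass in either comparison (-0.15; 0.268, and -0.05; 0.911). Non-peptidergic nociceptor markers were lower in NT3 than in vehicle rats with the weeks averaged (median -0.09, 3 of 13 positive; 0.0456, and adjusted p = 0.602 with an estimated correlation).

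The expression of Gsta6 varied widely among rats within 4 of the 6 groups. In week 11 NT3 libraries it ranged from 0.799 to 19.2 CPM, in week 5 NT3 libraries from 0.796 to 12.3, in week 11 vehicle libraries from 0.913 to 10.9 and in week 11 sham libraries from 0.531 to 7.58, while all 4 week 5 sham libraries lay between 0.609 and 0.937 and all 5 week 5 vehicle libraries between 8.56 and 16.3 CPM.

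Other splits of the libraries were fitted for each count of transcripts called by edgeR. Where the real arms or weeks gave 0, each of the 100 splits gave as many by definition, and the highest of the others was 459 for vehicle against sham over both weeks, 0 at week 5 and 4660 at week 11. It was 1, 0 and 0 for NT3 against vehicle, 3203, 1 and 6 for NT3 against sham, 2985 for week 11 against week 5 in sham rats and 0 in NT3 rats, and 2298 and 1 for the differences between the weeks of vehicle against sham and of NT3 against vehicle. The splits that called 2298 or more transcripts point to a structure of the samples that does not follow the arms.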
